A study of Arabidopsis thaliana with 24 samples.

How the data were processed

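Messenger RNA was measured by sequencing in Arabidopsis thaliana seedlings of 4 genotypes, each given a mock treatment or 150 µM ATP for 30 min. The genotypes were the wild type Col-0, the single mutants p2k1-3 and bdg-8, and the double mutant p2k1-3 bdg-8. The labels place 3 replicate samples in each of the 8 groups, which makes 24 libraries. Nothing in the labels says that replicates came from separate seedling cultures, so p-values measure only the spread between these samples, which may be technical. Per the labels' protocols, RNA was extracted with a plant RNA kit and DNase treatment, polyadenylated RNA was enriched, and the libraries were sequenced on 1 NovaSeq flow cell.

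The deposited values were raw counts of reads per gene, 1 table per library. Per the submitters' processing notes the tools were cutadapt 1.13, MultiQC 1.9, STAR 2.7.4a and HTSeq 0.13.5. Their settings, the genome build, the annotation and the strand setting of the counting were not given in the sources used here. Each table listed 33245 gene identifiers and 5 HTSeq summary entries. The summary entries (reads in no gene, ambiguous, not unique and similar) held 7.6 to 12.17% of each library's total and were left out of library sizes and tests. Ambiguous reads took 4.03 to 4.4%, and reads with more than 1 alignment took 3.13 to 7.59%. Genes of multigene families, such as the clustered lectin receptor kinases, can therefore have lost or exchanged reads and are uncertain, and so are overlapping and antisense genes. Gene symbols came from a gene table of the TAIR10.1 assembly, in which 33056 of the identifiers were found; 133 chloroplast and 56 mitochondrial identifiers were not. That table was used for names. Neighbouring genes were taken as those next in the order of the identifiers. No coordinates are given because the build used for counting is not known here. Where a symbol belonged to more than 1 locus, the identifier is printed alone.

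Library totals in genes ran from 25856588 to 35239775 counts, and 23193 to 23446 genes had at least 1 count. Groups were compared with edgeR 4.0.16 in R 4.3.3. Libraries were scaled with TMM factors, which ran from 0.954 to 1.07. Genes with low counts were removed with the default expression filter given the 8 groups, which left 20995 genes. A single quasi-likelihood model with 1 mean per group was fitted to all 24 libraries, with 16 residual degrees of freedom and a median biological coefficient of variation of 0.048. Each comparison was a contrast of that model, tested with the quasi-likelihood F-test. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and a gene was called at an adjusted p under 0.05. Log2 fold changes are given with standard errors derived from the F statistic. Levels are normalized counts scaled by library size (CPM), given as mean and SD over the 3 libraries of a group. Principal components used log2 CPM with a prior count of 2.

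The design gave 13 comparisons. ATP was compared with mock in each of the 4 genotypes. Without ATP, bdg-8 and p2k1-3 were compared with Col-0, and the double mutant with each single mutant. The genotype interaction asked whether the effect of bdg-8 without ATP differed between the p2k1-3 and Col-0 backgrounds. The other 4 interactions asked whether the ATP response differed between p2k1-3 and Col-0, between bdg-8 and Col-0, between the double mutant and bdg-8, and between the double mutant and p2k1-3. A further 3 results joined comparisons. They were the size of the ATP response in bdg-8 against Col-0 over genes called in the average ATP effect of both, the genes called in both measurements of the bdg-8 effect, and the bdg-8 effect on the genes that ATP changed in Col-0. The first and last of these were tested with fry of limma 3.58.1, which asks whether the genes of a set move one way on balance.

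The 18 gene lists held 280 members, all found in the tables. They covered jasmonate synthesis and signalling, calcium sensors and transport, stress transcription factors of the WRKY, ERF, ZAT and MYB families, pattern recognition and early immune signalling, salicylic acid defence, camalexin and indole glucosinolate synthesis, ethylene synthesis and feedback, cutin and wax synthesis, suberin synthesis, abscisic acid and dehydration response, lectin receptor kinases of clade I with apyrases, phosphate starvation response, heat shock proteins and the circadian clock. Markers of green tissue, root hairs, root endodermis and the mitotic cell cycle were included to show differences in the tissue sampled. Each list with at least 5 tested members was compared with all other genes by camera with a preset correlation of 0.01, and again with the correlation estimated from the data; both were adjusted over the 18 lists of a comparison. Counts called "adjusted over the list alone" used a Benjamini-Hochberg adjustment within the list.

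Genes were named by rule. P2K1 and BDG1 came first. In a comparison of 2 groups, the 8 largest rises and 8 largest falls were taken among called genes with a mean log2 CPM of at least 1 and no overlap between the libraries of the groups. In an interaction, the 5 largest in each direction were taken without the overlap condition. Of each list, up to 4 members with the smallest adjusted p were taken. A camalexin gene with 0 counts in every Col-0 mock library was left out of the text, because its fitted fold change depends on the prior count. The comparisons, the lists, the rule for named genes and the first 6 alternatives below were chosen before the data were examined.

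The first 6 alternatives were DESeq2 1.42.0 in place of edgeR, DESeq2 size factors in place of TMM, no expression filter, only the libraries of the groups compared, the replicate number as a block, and each library left out in turn. Fits with replicates 1 and 2 only, 1 and 3 only, and 2 and 3 only were added after seeing the data. Replicates were also compared within each group, by modelling each as a weighted mixture of the other 2 and dividing the remaining squared deviation by counting noise (an index of 1 is counting noise alone). No pair of libraries differed by as little as counting noise, so none was treated as deposited in duplicate.

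The code was tested on simulated data drawn from the real means and library sizes. The first simulation had 3 independent replicates per group and the spread estimated from all 24 libraries. For ATP in Col-0, edgeR called 89.6%, 95.5% and 100% of genes changed 1.5, 2 and 4 fold, with 8 unchanged genes among 20995 called. For the difference of ATP responses between bdg-8 and Col-0 it called 62.7%, 88.1% and 100%, with 14 unchanged genes called. A second simulation took the spread from replicates 1 and 2. There, 18 unchanged genes were called for ATP in Col-0 with independent replicates. With replicate 3 simulated as a pool of replicates 1 and 2, 483 were called. Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9 were used for figures.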

Results

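RNA sequencing was used to ask how seedlings with mutations in the extracellular ATP receptor gene P2K1, the cuticle gene BDG1, or both respond to ATP. P2K1 (also DORN1, AT5G60300) encodes the lectin receptor kinase that binds extracellular ATP, a signal released from wounded cells. BDG1 (AT1G64670) encodes an epidermal hydrolase needed for the cuticle, the waxy outer layer of the shoot. Counts per gene were analysed for 24 libraries from the wild type Col-0, both single mutants (p2k1-3 and bdg-8) and their double mutant, each after mock treatment or 150 µM ATP for 30 min, with 3 replicates per group. Libraries held 25856588 to 35239775 counts in genes. Log2 fold changes are given ± SE from edgeR with 3 libraries per group, and genes were called at an edgeR adjusted p under 0.05 among 20995 genes tested. Genes named as having the largest changes were taken among called genes with a mean log2 CPM of at least 1. Lists that camera called with its preset correlation and that are not described lost that call with an estimated correlation.

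The targeted genes were examined first. P2K1 transcript stood at 21.4 ± 0.821 CPM (SD, n = 3) in Col-0 mock and 12.1 ± 0.927 CPM in p2k1-3 mock, a fall of -0.82 ± 0.07 (edgeR adjusted p = 3.5e-08). In the double mutant it was 10.6 ± 0.478 CPM, a log2 difference of -1.15 ± 0.07 from bdg-8 (edgeR adjusted p = 1.5e-10). Transcript therefore remained in p2k1-3, and a count per gene does not show which part of the gene the reads came from. BDG1 transcript was 25.4 ± 0.451 CPM in Col-0 mock and 14.2 ± 1.77 CPM in bdg-8 mock, a fall of -0.84 ± 0.08 (edgeR adjusted p = 2.4e-08), and 15.3 ± 0.471 CPM in the double mutant, -0.60 ± 0.08 against p2k1-3 (edgeR adjusted p = 2e-06). ATP raised BDG1 transcript in both genotypes that carry bdg-8. It reached 107 ± 9.87 CPM in bdg-8, a log2 rise of 2.91 ± 0.07 (edgeR adjusted p = 1e-20), and 112 ± 2.28 CPM in the double mutant, a log2 rise of 2.87 ± 0.07 (edgeR adjusted p = 1.4e-20). In Col-0 and p2k1-3 the log2 values with ATP were 0.04 ± 0.07 and 0.08 ± 0.07, neither of them called. The difference between the ATP responses of bdg-8 and Col-0 was 2.88 ± 0.10 for BDG1 (edgeR adjusted p = 2.5e-15). P2K1 rose modestly with ATP in Col-0 (0.31 ± 0.06) and in bdg-8 (0.48 ± 0.06). In p2k1-3 and the double mutant it had values of 0.10 ± 0.07 and 0.06 ± 0.07.

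**Figure D1:**
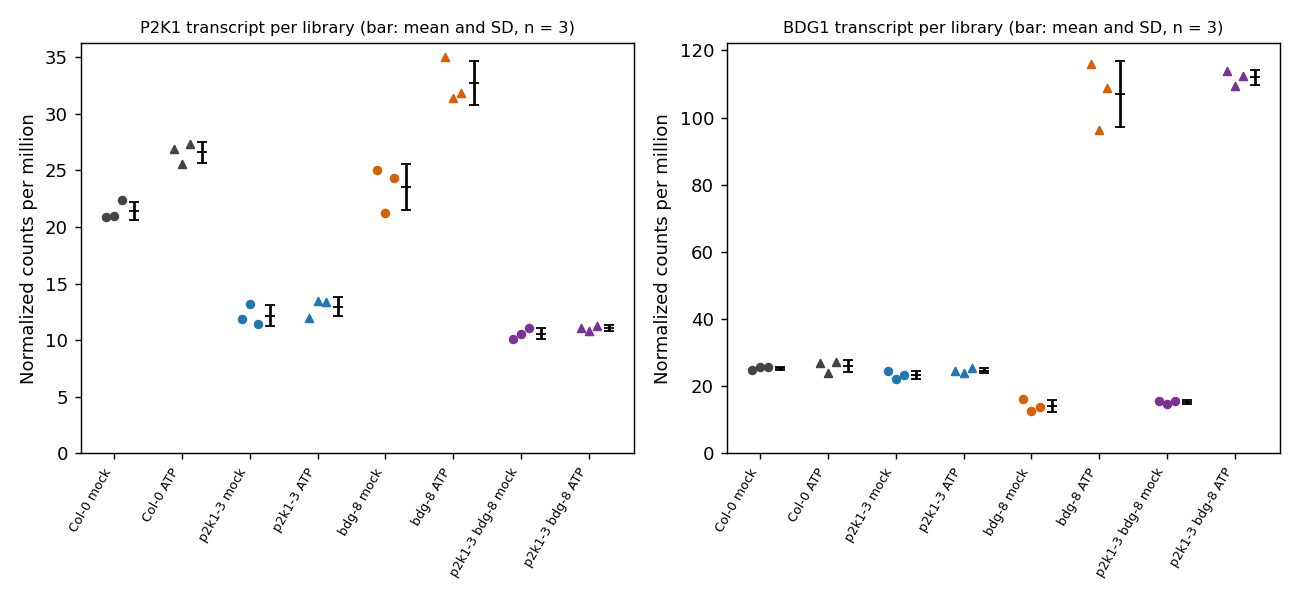
Normalized CPM of P2K1 (left) and BDG1 (right) in each of the 24 libraries by group, with circles for mock, triangles for ATP, and black bars for the mean and SD of 3 libraries. P2K1 lay near 12.1 in p2k1-3 mock against 21.4 in Col-0 mock, and BDG1 rose to 107 in bdg-8 and 112 in the double mutant with ATP.

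Treatment and the bdg-8 genotype separated the libraries. The first principal component, with 50.5% of the variance, placed every ATP library above every mock library, and the second, with 20.7%, placed every library that carries bdg-8 below every other library. Correlations of log2 CPM across genes were 0.9922 to 0.9955 within groups and 0.9464 to 0.9941 between groups (genes are not independent, so these describe the libraries only). Within every one of the 8 groups, replicate 3 lay between replicates 1 and 2, with a weight of replicate 1 between 0.375 and 0.525 in the best mixture. The number of genes called with replicates 1 and 2 alone, a setting chosen after seeing the data, is therefore given beside each count. Having fewer libraries can also lower it, but does not account for the whole drop. For ATP in Col-0, the 4585 genes called with all libraries became 2494 with replicates 1 and 2. Pairs of the same size that include replicate 3 gave 4066 (1 and 3) and 4564 (2 and 3).

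**Figure D2:**
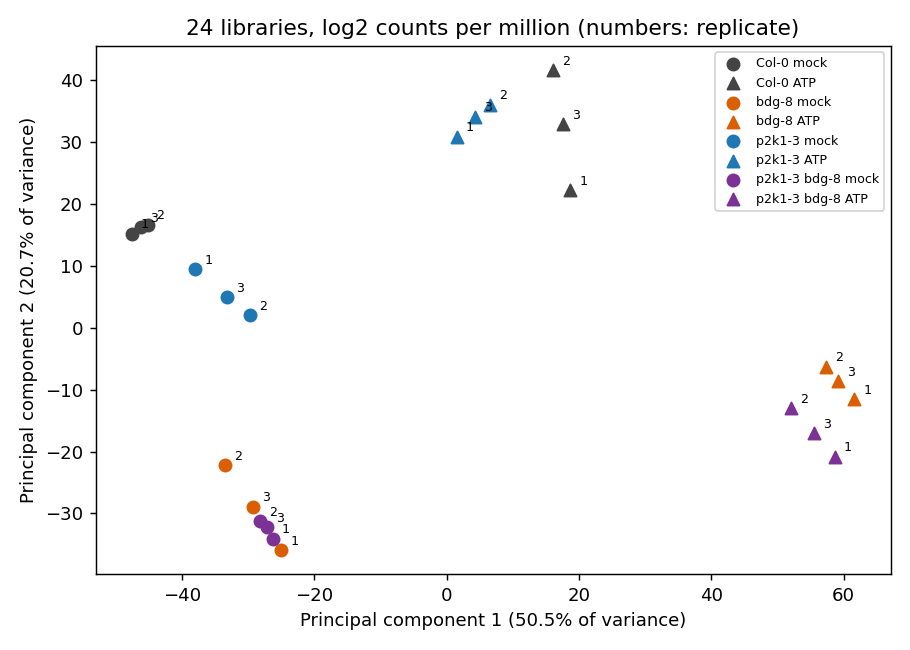
The 24 libraries on the first and second principal components of log2 CPM, with 1 point per library, colours for genotype, circles for mock, triangles for ATP, and numbers for the replicate. The axes hold 50.5% and 20.7% of the variance, and on both of them replicate 3 lies between replicates 1 and 2 in each of the 8 groups.

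The response of the wild type to ATP was examined next. Genes of calcium signalling, stress transcription factors, early immune signalling and ethylene synthesis rose within 30 min of ATP in Col-0. The largest rises included AT1G33760, an AP2/ERF transcription factor gene, at 6.93 ± 0.19 (122-fold, edgeR adjusted p = 6.6e-19), ERF13 at 5.64 ± 0.19, the calmodulin-like gene CML37 at 5.15 ± 0.39 and the glutaredoxin gene GRXC9 at 5.08 ± 0.35. The largest falls were smaller, from AT5G20790 at -2.08 ± 0.24 and AT2G43870 at -1.95 ± 0.19 to the phosphate-starvation gene GDPD1 at -1.53 ± 0.18, with the glycerol-3-phosphate permease gene G3Pp1 at -1.63 ± 0.11. In all, 4585 genes were called, of which 2765 rose and 1820 fell; 785 rose and 120 fell at least 2 fold. With replicates 1 and 2 alone 2494 genes were called, and 2474 of the 4585 (54%) kept their call.

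Of the 15 calcium genes tested, 13 rose, 0 fell and 2 were not called, with a median of 2.38 (camera adjusted p = 5.7e-17; 13 rose adjusted over the list alone). The calcium-dependent kinase genes CPK28 and CPK32 rose by 2.64 ± 0.07 and 2.25 ± 0.07, and the calmodulin-like gene TCH3 by 3.25 ± 0.13. Of 32 stress transcription factors, 26 rose and 1 fell, 27 and 2 adjusted over the list alone (camera adjusted p = 1.9e-21), with WRKY33 at 3.03 ± 0.12 and MYB51, an activator of indole glucosinolate synthesis, at 3.20 ± 0.10. Of 28 genes for pattern recognition and early immune signalling, 22 rose and 0 fell by either adjustment, over all genes or adjusted over the list alone (camera adjusted p = 8.1e-18). Among them, the MAP kinase gene MPK3 rose by 2.20 ± 0.06 and RBOHD, which encodes the NADPH oxidase of the immune oxidative burst, by 1.73 ± 0.07. The ethylene list had 4 rises and 1 fall among 6 genes, the same numbers adjusted over the list alone (camera adjusted p = 0.00041), with ACS6, an enzyme of the committed step of ethylene synthesis, at 2.56 ± 0.10. These 4 calls held with an estimated correlation, at camera adjusted p = 0.0033, 0.026, 0.019 and 0.048 in the order given.

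Of 23 jasmonate genes, 17 rose and 1 fell, 17 and 4 adjusted over the list alone (camera adjusted p = 3.6e-10, but adjusted p = 0.073 with an estimated correlation). LOX4 and AOC3 of jasmonate synthesis rose by 4.24 ± 0.17 and 2.36 ± 0.10, and JAZ1, a repressor of the pathway, by 2.20 ± 0.10. Of 17 salicylic acid genes, 9 rose and 0 fell, 10 and 0 adjusted over the list alone (camera adjusted p = 1.6e-07, but adjusted p = 0.073 with an estimated correlation). SARD1 and CBP60g, transcription factor genes that activate salicylic acid synthesis, rose by 3.55 ± 0.14 and 3.36 ± 0.18. Phosphate starvation genes had 5 falls and 1 rise among 15, the same adjusted over the list alone (camera adjusted p = 0.04, but adjusted p = 0.5 with an estimated correlation), with SPX1 at -1.20 ± 0.15. Suberin genes had 2 falls among 11, 4 adjusted over the list alone (camera adjusted p = 0.037, but adjusted p = 0.5 with an estimated correlation). None of the 10 other lists was called by camera in Col-0, with adjusted p of 0.11 or more. In these, the counts of rises and falls, with those adjusted over the list alone in brackets, were 6 and 6 of 32 cutin and wax genes [7 and 6], 2 and 2 of 12 camalexin and glucosinolate genes [2 and 2], 5 and 1 of 15 dehydration genes [6 and 1], 2 and 1 of 11 lectin receptor kinases and apyrases [2 and 1], 1 and 3 of 6 heat shock genes [1 and 4], and 3 and 3 of 10 clock genes [4 and 4]. Among markers of tissue, 0 of 9 green tissue genes were called [0], 1 of 5 root hair genes fell [3], 1 of 10 root endodermis genes fell [1] and 1 of 8 mitotic genes fell [1].

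To see what part of this response needed P2K1, ATP was compared with mock in p2k1-3, and the difference between the responses was tested. In p2k1-3, ATP still raised AT1G33760 (5.80 ± 0.18), the stress transcription factor gene ZAT7 (4.79 ± 0.28), the ethylene synthesis gene ACS11 (3.80 ± 0.13) and CML37 (3.79 ± 0.38). The largest falls included AT2G17740 (-2.52 ± 0.27), the receptor-like kinase gene CRK6 (-2.18 ± 0.27) and AT1G26420 (-2.08 ± 0.29). In all, 4287 genes were called, with 2497 rises (449 at least 2 fold) and 1790 falls (167 at least 2 fold). The first 2 replicates alone gave 1883, and 1874 of the 4287 (43.7%) kept their call. Of the 2765 genes that rose in Col-0, 1850 (66.9%) rose in p2k1-3, where independent lists would share 329; 741 falls were shared (155 for independent lists) and 42 genes were called in opposite directions. The correlation of fold changes across genes, which are not independent, was 0.69.

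Calcium genes rose in p2k1-3 in 12 of 15 cases, also 12 adjusted over the list alone, with a median of 1.27 (camera adjusted p = 5.7e-13 and 0.011 with an estimated correlation). Stress transcription factors had 21 rises and 4 falls, the same adjusted over the list alone (camera adjusted p = 3.7e-10, but adjusted p = 0.36 with an estimated correlation). Jasmonate genes had 14 rises and 1 fall, again the same adjusted over the list alone (camera adjusted p = 2e-05, but adjusted p = 0.42 with an estimated correlation). Pattern recognition genes had 13 rises and 4 falls, 13 and 5 adjusted over the list alone, and a median of 0.19 (camera adjusted p = 0.00041, but adjusted p = 0.43 with an estimated correlation). Root hair markers fell in 3 of 5 cases by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 0.025, but adjusted p = 0.43 with an estimated correlation). The expansin gene EXPA18 was among them at -0.50 ± 0.11. In p2k1-3 the camalexin and glucosinolate list moved down and the cutin and wax list up. Of the former 5 of 12 fell and 1 rose, 8 and 1 adjusted over the list alone; of the latter 12 of 32 rose and 3 fell, 14 and 5 adjusted over the list alone (camera adjusted p = 0.0053 for both, but adjusted p = 0.43 for both with an estimated correlation). KCS1, an elongase gene of wax synthesis, rose by 0.97 ± 0.06. Salicylic acid genes had 7 rises, 7 adjusted over the list alone, and ethylene genes 3, 4 with 2 falls adjusted over the list alone (camera adjusted p = 0.0053 and 0.016, but adjusted p = 0.43 and 0.37 with an estimated correlation).

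The fold change with ATP was smaller in p2k1-3 than in Col-0 for genes of defence, some of which were higher in p2k1-3 before ATP. TAT3, a jasmonate-responsive aminotransferase gene, rose by 3.99 in Col-0 and had a value of -1.27 in p2k1-3, a difference of -5.27 ± 0.65 (edgeR adjusted p = 9.9e-06). ERF13 rose by 5.64 in Col-0 and 2.09 in p2k1-3 (-3.54 ± 0.38), the cytochrome P450 gene CYP706A2 by 4.62 and 1.21 (-3.41 ± 0.37), and WRKY40 by 4.52 and 1.71 (-2.81 ± 0.29). In the other direction, the glutathione transferase gene GSTU24 (1.25 ± 0.24) and the phospholipase gene NPC4 (0.99 ± 0.25) had higher responses in p2k1-3. In all, 940 genes differed, 143 higher and 797 lower in p2k1-3 (11 and 224 at least 2 fold). Limiting the data to replicates 1 and 2 left 149 called, all among the 940 (15.9%). TAT3, ERF13 and CYP706A2 were called there too, and the other 7 of the 10 largest differences were not. All 10 kept their sign, with GSTU24 and NPC4 at 1.27 and 1.12.

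Lower responses in p2k1-3 were called for 20 of 32 stress transcription factors (23 adjusted over the list alone; camera adjusted p = 2e-22), 15 of 28 pattern recognition genes (24 adjusted over the list alone; camera adjusted p = 1.4e-24) and 9 of 15 calcium genes (9 adjusted over the list alone; camera adjusted p = 1.2e-09). These calls held with an estimated correlation (camera adjusted p = 0.023, 0.0087 and 0.023), and examples were MYB51 at -1.51 ± 0.14, MPK3 at -0.74 ± 0.09 and CPK28 at -0.80 ± 0.09. Jasmonate genes were lower in 9 of 23 cases, 11 adjusted over the list alone with 2 higher (camera adjusted p = 2.6e-07, but adjusted p = 0.17 with an estimated correlation), and salicylic acid genes in 7 of 17, 10 adjusted over the list alone (camera adjusted p = 3.8e-09, but adjusted p = 0.057 with an estimated correlation). JAZ10 (-1.72 ± 0.21) and SARD1 (-1.96 ± 0.19) were among them. Between p2k1-3 and Col-0, stress transcription factors had a median log2 difference of 0.54 in mock and -0.33 with ATP, with 18 called higher in mock and 12 lower with ATP. Pattern recognition genes had medians of 0.26 and -0.24, with 14 and 9 called, and calcium genes 0.16 and -0.47, with 1 and 9 called.

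**Figure D3:**
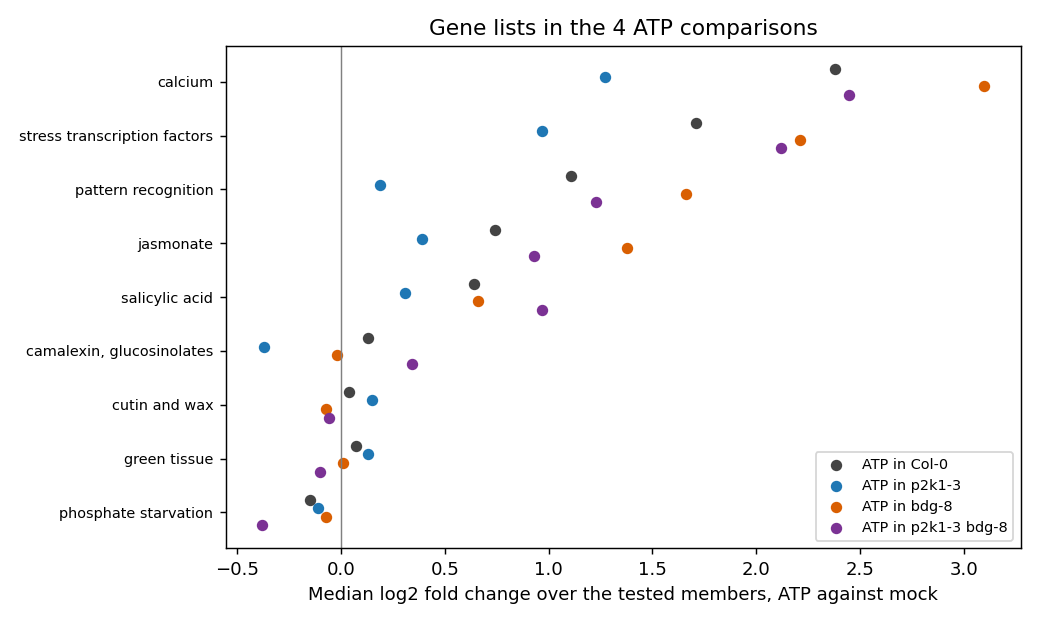
Median log2 fold change of ATP against mock over the tested members of 9 gene lists (vertical axis), with 1 point for each of the 4 genotypes. Calcium genes had a median of 2.38 in Col-0, 1.27 in p2k1-3, 3.10 in bdg-8 and 2.45 in the double mutant.

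The same treatment was then followed in the cuticle mutant. In bdg-8, ATP raised AT1G33760 by 8.10 ± 0.17, ERF13 by 6.62 ± 0.16, CML37 by 6.60 ± 0.31 and ZAT7 by 6.29 ± 0.23. The largest falls included PKS4, a phytochrome-interacting protein gene of phototropism (-2.82 ± 0.36), the carotenoid cleavage gene NCED4 (-2.52 ± 0.22) and the expansin gene EXPA1 (-2.13 ± 0.07). In all, 7631 genes were called, with 3916 rises (1254 at least 2 fold) and 3715 falls (361 at least 2 fold). Without replicate 3 in any group, 4852 were called, and 4808 of the 7631 (63%) kept their call. Of the genes that rose in Col-0, 2532 (91.6%) also rose in bdg-8, where independent lists would share 516, and fold changes correlated at 0.86 across genes.

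Calcium genes had 13 rises among 15 in bdg-8, 13 adjusted over the list alone (camera adjusted p = 2.8e-14 and 0.0095 with an estimated correlation). Stress transcription factors had 28 rises and 3 falls by both adjustments, over all genes and adjusted over the list alone (camera adjusted p = 1.2e-18 and 0.043 with an estimated correlation). Pattern recognition genes had 24 rises and 1 fall, unchanged when adjusted over the list alone (camera adjusted p = 4.9e-17 and 0.022 with an estimated correlation), and ethylene genes 4 rises, 4 adjusted over the list alone (camera adjusted p = 0.00038 and 0.043 with an estimated correlation). Jasmonate genes had 16 rises and 1 fall, 16 and 2 adjusted over the list alone (camera adjusted p = 5.1e-10, but adjusted p = 0.088 with an estimated correlation), with CYP94C1, which breaks down active jasmonate, at 4.83 ± 0.14. Salicylic acid genes had 8 rises, 8 with 1 fall adjusted over the list alone (camera adjusted p = 7.5e-05, but adjusted p = 0.22 with an estimated correlation).

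The ATP response was larger in bdg-8 than in Col-0. Over the 4201 genes that rose in the average of both genotypes, the median difference of the responses was 0.189 and 85% rose more in bdg-8 (fry adjusted p = 4.2e-10). Over the 4389 genes that fell, the median difference was 0.105 towards a deeper fall and 75.9% fell further in bdg-8 (fry adjusted p = 4.8e-07). Gene by gene, 1660 responses differed, 1209 higher and 451 lower in bdg-8 (120 and 70 at least 2 fold). The count was 458 with replicates 1 and 2 alone, of which 456 (27.5% of the 1660) were shared. After BDG1 itself, the largest higher responses included those of the jasmonate repressor JAZ7 (5.36 in bdg-8, 2.75 in Col-0, difference 2.61 ± 0.77), the sugar transporter gene SWEET10 (2.05 ± 0.38) and the immune receptor-like kinase gene FRK1 (1.85 ± 0.56). TAT3 had a lower response, at 0.70 in bdg-8 and 3.99 in Col-0 (-3.30 ± 0.55), whose level without ATP was already higher in bdg-8. Besides BDG1, 0 of the 9 other genes with the largest differences were called with replicates 1 and 2 alone, and all 9 kept their sign.

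In this test, responses were higher in bdg-8 for 12 of 28 pattern recognition genes (14 adjusted over the list alone; camera adjusted p = 7e-10, but adjusted p = 0.13 with an estimated correlation), 5 of 15 calcium genes (6 adjusted over the list alone; camera adjusted p = 3.8e-06, but adjusted p = 0.13 with an estimated correlation), 8 of 32 stress transcription factors (10 adjusted over the list alone; camera adjusted p = 2.6e-05, but adjusted p = 0.36 with an estimated correlation) and 7 of 23 jasmonate genes (9 adjusted over the list alone; camera adjusted p = 4.1e-05, but adjusted p = 0.36 with an estimated correlation). MPK3 (0.87 ± 0.09), CPK28 (0.92 ± 0.09), MYB44 (0.53 ± 0.07) and the jasmonate synthesis gene LOX3 (1.43 ± 0.17) were called both with all libraries and with replicates 1 and 2 alone. Heat shock genes had higher responses in 3 of 6 cases, 4 adjusted over the list alone (camera adjusted p = 0.00085, but adjusted p = 0.25 with an estimated correlation), with the heat shock factor gene HSFA2 at 1.32 ± 0.25. Cutin and wax genes had 3 higher and 2 lower responses, 3 and 4 adjusted over the list alone (camera adjusted p = 0.8); MYB96, a regulator of wax synthesis, was higher by 0.80 ± 0.10 and the cutin regulator MYB16 lower at -0.97 ± 0.17.

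Next, ATP was given to plants that carry both mutations. In the double mutant, ATP raised AT1G33760 by 7.41 ± 0.16, ZAT7 by 6.34 ± 0.24, CML37 by 5.56 ± 0.29 and PHI-1 by 5.39 ± 0.11. The largest falls included AT5G20790 (-2.62 ± 0.31), the cytochrome P450 gene CYP78A6 (-2.57 ± 0.17) and the kinase gene WAG1 (-2.11 ± 0.13). In all, 7070 genes were called, with 3598 rises (1148 at least 2 fold) and 3472 falls (281 at least 2 fold). Using replicates 1 and 2 alone, 4269 were called, and 4226 of the 7070 (59.8%) kept their call. Of the 3916 genes that rose in bdg-8, 3087 (78.8%) rose in the double mutant, where independent lists would share 671, and fold changes correlated at 0.89 across genes.

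Calcium genes had 13 rises, stress transcription factors 28 rises and 3 falls, pattern recognition genes 23 rises and ethylene genes 4 rises and 1 fall. Adjusted over the list alone these were 13 and 0, 29 and 3, 23 and 0, and 4 and 1 (camera adjusted p = 1.7e-14, 4.6e-21, 1.3e-17 and 0.00027 in that order, and 0.0083, 0.028, 0.019 and 0.04 with an estimated correlation). Salicylic acid genes had 13 rises among 17, 14 adjusted over the list alone (camera adjusted p = 6.4e-09, but adjusted p = 0.053 with an estimated correlation), with SARD1 at 4.26 ± 0.11. Jasmonate genes had 16 rises and 2 falls, 17 and 2 adjusted over the list alone (camera adjusted p = 6.1e-10, but adjusted p = 0.075 with an estimated correlation).

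FRK1, WRKY30, SARD1 and ACS7 had higher ATP responses in the double mutant than in p2k1-3. FRK1 rose by 1.97 in the double mutant and had a value of -1.92 in p2k1-3 (3.89 ± 0.47, edgeR adjusted p = 1.1e-06). WRKY30 gave 1.02 and -2.99 (4.02 ± 0.33), SARD1 4.26 and 1.59 (2.67 ± 0.17), and the ethylene synthesis gene ACS7 3.06 and 0.28 (2.78 ± 0.18). Without ATP, FRK1 was already higher in p2k1-3, at 48.1 ± 26.6 CPM against 7.88 ± 2.63 CPM (SD, n = 3) in the double mutant, a log2 difference of -2.59. WRKY30 was at 4.21 ± 0.552 against 0.841 ± 0.186 CPM, a log2 difference of -2.30. The defensin gene PDF1.2 (-2.38 ± 0.58) and PKS4 (-1.69 ± 0.37) had lower responses in the double mutant. In all, 3406 genes differed, 2067 higher and 1339 lower (593 and 111 at least 2 fold). From replicates 1 and 2 alone came 1267, of which 1258 (36.9% of the 3406) were shared. Of the 10 largest differences 5 were called there, all of them higher responses, and all 10 kept their sign. PDF1.2 and PKS4 were not called there, at -2.33 and -1.6. Higher responses were called for 22 of 28 pattern recognition genes, 27 of 32 stress transcription factors with 1 lower, 12 of 17 salicylic acid genes with 1 lower and 7 of 15 calcium genes. Adjusted over the list alone, the higher counts were 25, 27, 13 and 9 (camera adjusted p = 7.5e-23, 7.5e-23, 3e-09 and 9.5e-08 in that order, and 0.0079, 0.032, 0.041 and 0.041 with an estimated correlation). Green tissue markers had lower responses in 4 of 9 cases, 5 adjusted over the list alone (camera adjusted p = 0.0035, but adjusted p = 0.3 with an estimated correlation), with the light-harvesting gene LHCB2.1 at -0.69 ± 0.15.

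The double mutant was also compared with bdg-8, to see what p2k1-3 changed in the response of the cuticle mutant. The calmodulin-like gene CML39 rose by 5.43 in bdg-8 and 1.93 in the double mutant (-3.50 ± 0.47), and responses were lower for the jasmonate repressor genes JAZ2 (-0.82 ± 0.10) and JAZ3 (-0.54 ± 0.10). Neither of these was called with replicates 1 and 2 alone (-0.88 and -0.62). Higher responses were called for the acetyltransferase gene NATA1 (3.42 ± 0.59) and for PBS3, an enzyme gene of salicylic acid synthesis (2.38 ± 0.43). In all, 134 genes differed, 32 higher and 102 lower (14 and 16 at least 2 fold), but 2 were called with replicates 1 and 2 alone, both among the 134 (1.5%). Of the 10 largest differences 0 were called there, and all 10 kept their sign, with CML39, NATA1 and PBS3 at -3.9, 3.5 and 2.62. With only the groups compared in the fit, 71 genes were higher and 75 lower. Calcium genes were lower in 1 of 15 cases, 6 adjusted over the list alone (camera adjusted p = 1.5e-05, but adjusted p = 0.24 with an estimated correlation), and jasmonate genes in 3 of 23 with 1 higher, also 3 and 1 adjusted over the list alone (camera adjusted p = 0.0023, but adjusted p = 0.45 with an estimated correlation). Root hair, green tissue and mitotic markers had 0 called members by edgeR, also 0 adjusted over the list alone, with medians of -0.21, -0.16 and 0.13 (camera adjusted p = 0.041, 0.016 and 0.012, but adjusted p = 0.45, 0.47 and 0.45 with an estimated correlation). With the replicate number as a block, root hair markers were not called (camera adjusted p = 0.057).

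The effect of bdg-8 without ATP was measured in both backgrounds. In bdg-8 mock, transcripts of TAT3 (4.14 ± 0.44), the farnesoic acid methyltransferase gene FAMT (3.65 ± 0.37) and the immune receptor gene RLP23 (2.85 ± 0.35) were higher than in Col-0. The detoxification genes CYP81D11 (-5.58 ± 0.30), UGT74E2 (-3.60 ± 0.59) and DOGT1 (-2.42 ± 0.26) were lower; CYP81D11 was at 0.94 ± 0.499 CPM (SD, n = 3) against 44.7 ± 16.2 CPM. In all, 7662 genes were called, 3778 higher and 3884 lower, with 272 and 248 of these at least 2 fold. In all, 3170 were called with replicates 1 and 2 alone, and 3146 of the 7662 (41.1%) kept their call.

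Salicylic acid genes were higher in bdg-8 mock in 12 of 17 cases and stress transcription factors in 16 of 32, with 0 lower in either and the same counts adjusted over the list alone (camera adjusted p = 0.00011 for both, but adjusted p = 0.39 for both with an estimated correlation). SARD1 (1.49 ± 0.17), EDS1 (0.39 ± 0.06) and WRKY18 (0.62 ± 0.09) were among them. Jasmonate genes were higher in 11 of 23 cases, 11 adjusted over the list alone (camera adjusted p = 0.0031, but adjusted p = 0.43 with an estimated correlation), with LOX2 at 0.98 ± 0.11. Of the camalexin and glucosinolate genes 7 of 12 were higher, 8 adjusted over the list alone (camera adjusted p = 0.0013, but adjusted p = 0.39 with an estimated correlation), with PAD3, the last enzyme of camalexin synthesis, at 1.15 ± 0.21. Alongside these groups, all 9 green tissue markers were lower, 9 adjusted over the list alone (camera adjusted p = 7.6e-05, but adjusted p = 0.39 with an estimated correlation), with the Rubisco gene RBCS2B at -0.65 ± 0.08, and the 10 most abundant genes took 5.1 to 6.63% of counts in bdg-8 mock libraries against 7.16 to 7.35% in Col-0 mock. Mitotic genes were lower in 7 of 8 cases, 7 adjusted over the list alone (camera adjusted p = 0.0031, but adjusted p = 0.39 with an estimated correlation), with the cytokinesis gene KNOLLE at -0.42 ± 0.08. Heat shock genes were lower in 5 of 6 and phosphate starvation genes in 9 of 15, with 1 and 3 higher, and the same counts adjusted over the list alone (camera adjusted p = 0.0031 and 0.023, but adjusted p = 0.39 and 0.43 with an estimated correlation). HSP70 was at -1.39 ± 0.15 and the galactolipid synthesis gene MGD3 at -2.23 ± 0.27. Cutin and wax genes were lower in 12 of 32 and higher in 4, 12 and 5 adjusted over the list alone (camera adjusted p = 0.039, but adjusted p = 0.57 with an estimated correlation), with GPAT8 at -0.50 ± 0.06 and BDG2, a paralog of BDG1, at 0.64 ± 0.08.

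In the p2k1-3 background, CYP81D11 was again lower with bdg-8 (-7.03 ± 0.40). FRK1 (-2.59 ± 0.34) and WRKY30 (-2.30 ± 0.21) were lower in the double mutant than in p2k1-3. Both were higher in p2k1-3 than in Col-0 without ATP, by 2.45 and 3.6. The sugar phosphate translocator gene GPT2 (2.52 ± 0.21), the amylase gene BAM5 (2.46 ± 0.20) and the anthocyanin synthesis genes DFR (2.40 ± 0.18) and LDOX (2.24 ± 0.17) were higher in the double mutant than in p2k1-3. In all, 6555 genes were called, 3180 higher and 3375 lower (191 and 292 at least 2 fold). Again with replicates 1 and 2 alone, 2161 were called, and 2148 of the 6555 (32.8%) kept their call. Jasmonate genes were higher in 11 of 23 cases and green tissue markers lower in 7 of 9, 11 and 8 adjusted over the list alone (camera adjusted p = 0.00035 and 0.00082, but adjusted p = 0.58 for both with an estimated correlation). Suberin genes were higher in 6 of 11 with 1 lower, 8 and 1 adjusted over the list alone (camera adjusted p = 0.014, but adjusted p = 0.58 with an estimated correlation), with ASFT, a feruloyl transferase gene of suberin, at 0.42 ± 0.08. Mitotic genes were lower in 5 of 8, 5 adjusted over the list alone (camera adjusted p = 0.0091, but adjusted p = 0.58 with an estimated correlation).

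The 2 measurements of the bdg-8 effect share no library. They had 4523 genes called in the same direction, 2162 higher (572 for independent lists) and 2361 lower (624 for independent lists), with 96 called in opposite directions and a correlation of fold changes of 0.61 across genes. With replicates 1 and 2 alone, 1354 genes were shared. The genes that ATP changed in Col-0 were then followed in the double mutant against p2k1-3 without ATP, again with no library in common. The 2765 genes that rose with ATP had a median of -0.010 (fry adjusted p = 0.44), and the 1820 genes that fell had a median of -0.022 (fry adjusted p = 0.03). The second value depended on the libraries, since it was 0.019 without Col-0 ATP replicate 1 and 0.025 with replicates 2 and 3 alone.

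Genes of defence were among those that differed between p2k1-3 and Col-0 without ATP. WRKY30 was higher by 3.60 ± 0.25 (edgeR adjusted p = 1e-09), the indole glucosinolate methyltransferase gene IGMT2 by 2.57 ± 0.21, CYP81F2, a P450 gene of the same pathway, by 1.47 ± 0.11, and FRK1 by 2.45 ± 0.33, at 48.1 ± 26.6 CPM against 8.80 ± 0.881 CPM (SD, n = 3). AT2G01422 fell from 24.6 ± 0.555 CPM to 0.0739 ± 0.0422 CPM, and AT1G75945 rose from 0.117 ± 0.047 to 3.89 ± 1.24 CPM. The chromatin protein gene HMGB5 (-1.31 ± 0.08) and the cold-response gene KIN1 (-1.49 ± 0.24) were lower in p2k1-3. In all, 1111 genes were called, 715 higher and 396 lower (176 and 39 at least 2 fold). In all, 85 were called with replicates 1 and 2 alone, all among the 1111 (7.7%), and 6 of the 16 largest changes. FRK1 and KIN1 were among those no longer called, at 2.47 and -1.44 there.

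Stress transcription factors were higher in p2k1-3 mock in 18 of 32 cases, pattern recognition genes in 14 of 28 and salicylic acid genes in 7 of 17, with 0 lower; adjusted over the list alone these were 23, 18 and 11 (camera adjusted p = 4.7e-18, 3.1e-16 and 5e-08, but adjusted p = 0.07, 0.053 and 0.082 with an estimated correlation). Examples were WRKY53 (2.23 ± 0.25), SOBIR1, an adaptor kinase gene of receptor-like proteins (0.84 ± 0.11), and SARD1 (1.48 ± 0.17). Suberin genes were lower in 4 of 11, 5 adjusted over the list alone, and dehydration genes in 2 of 15, 6 adjusted over the list alone (camera adjusted p = 4.1e-05 and 6.9e-05, but adjusted p = 0.17 and 0.24 with an estimated correlation). Of the green tissue markers 0 were called, by either adjustment, with a median of -0.17 (camera adjusted p = 0.01, but adjusted p = 0.44 with an estimated correlation). Root endodermis markers were likewise not called over all genes, with 2 lower adjusted over the list alone and a median of -0.15 (camera adjusted p = 0.0099, but adjusted p = 0.24 with an estimated correlation).

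The effect of p2k1-3 without ATP was also measured in the bdg-8 background. AT1G75945, at 9.87 ± 0.289 against 0.112 CPM, and the MADS-box gene AGL87 (2.85 ± 0.15) were higher in the double mutant than in bdg-8, and AT2G01422 (-3.77 ± 0.33), the isochorismate synthase gene ICS2 (-1.53 ± 0.25) and the osmotin gene OSM34 (-1.07 ± 0.15) were lower. In all, 140 genes were called, 80 higher and 60 lower (8 and 17 at least 2 fold). Of these, 6 (4.3%) and no other genes were called with replicates 1 and 2 alone. Of the genes named here, ICS2 and OSM34 were no longer called, at -1.49 and -1.05 there. With only the groups compared in the fit, 14 genes were higher and 43 lower. The effects of p2k1-3 in the 2 backgrounds, which share no library, had 13 higher and 24 lower genes in common (3 and 1 for independent lists). Another 4 genes were called in opposite directions, and the correlation of fold changes across genes was 0.21. Cutin and wax genes had 1 called member, 4 adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.00013, but adjusted p = 0.52 with an estimated correlation). Salicylic acid genes had 0 called members over all genes or adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.0022, but adjusted p = 0.52 with an estimated correlation), and the lectin receptor kinases and apyrases had 3 higher, 3 adjusted over the list alone (camera adjusted p = 0.0022, but adjusted p = 0.13 with an estimated correlation). Root endodermis markers had 0 called members and 1 lower adjusted over the list alone, with a median of -0.17 (camera adjusted p = 0.0048, but adjusted p = 0.41 with an estimated correlation).

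The interaction of the genotypes without ATP asked whether the effects of the mutations added up on the log2 scale. For MYB51, the bdg-8 effect was 0.22 in Col-0 and -1.04 in p2k1-3, a difference of -1.26 ± 0.17 (edgeR adjusted p = 0.00024). WRKY30 (-3.60 ± 0.38), CYP81F2 (-1.52 ± 0.16) and SARD1 (-1.81 ± 0.22) differed in the same direction. In all, 416 genes were called, 120 with a higher and 296 with a lower value in the double mutant than the sum of the single effects (5 and 153 at least 2 fold), but 2 were called with replicates 1 and 2 alone, both among the 416 (0.5%). WRKY30 was called there, while MYB51, CYP81F2 and SARD1 were not, at -1.41, -1.5 and -1.88. Of the 10 largest interactions among genes with a mean log2 CPM of at least 1, 0 were called there, and all 10 kept their sign. Stress transcription factors were lower in 8 of 32 cases (20 adjusted over the list alone; camera adjusted p = 1.2e-16, but adjusted p = 0.061 with an estimated correlation), pattern recognition genes in 8 of 28 (10 adjusted over the list alone; camera adjusted p = 3.4e-12, but adjusted p = 0.061 with an estimated correlation) and salicylic acid genes in 7 of 17 (12 adjusted over the list alone; camera adjusted p = 3.4e-12, but adjusted p = 0.061 with an estimated correlation). Cutin and wax genes were higher in 2 of 32, 6 adjusted over the list alone (camera adjusted p = 1.5e-09, but adjusted p = 0.085 with an estimated correlation), with GPAT4 at 0.27 ± 0.06.

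**Figure D4:**
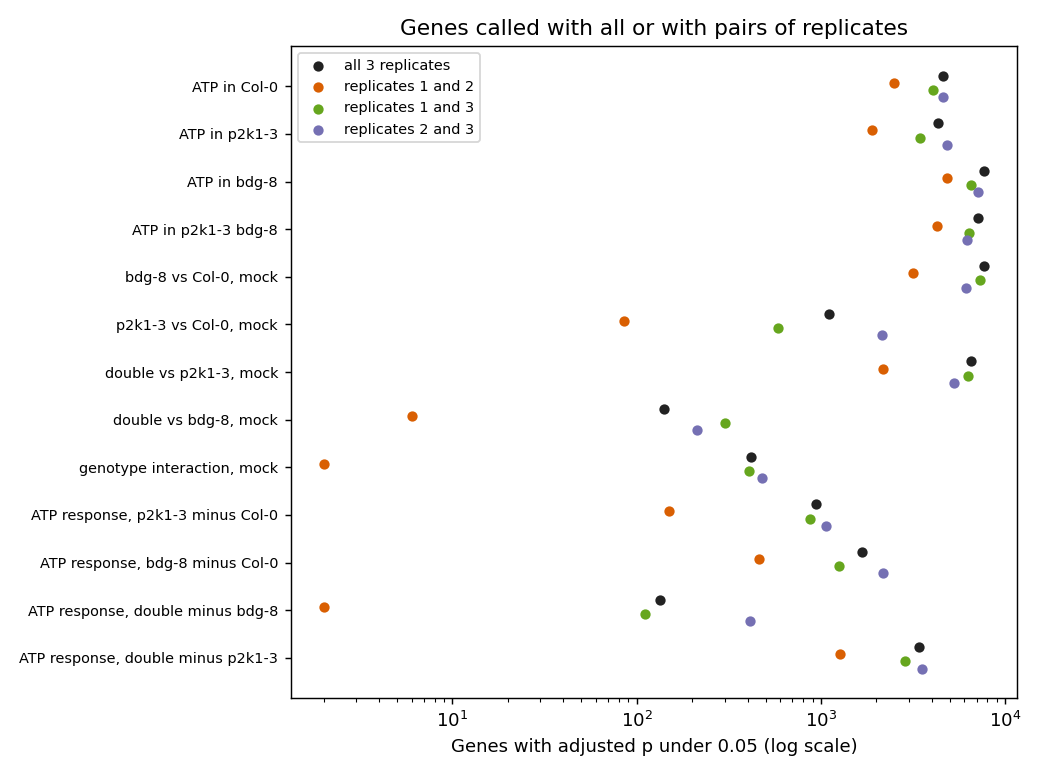
Number of genes called (horizontal log axis) in each of the 13 comparisons with all 3 replicates and with each pair of replicates, 1 point per setting. Replicates 1 and 2 gave the lowest count in each comparison, as for the p2k1-3 effect without ATP, where 1111 genes were called with all replicates and 85, 583 and 2135 with pairs 1 and 2, 1 and 3, and 2 and 3.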

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

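The splits of the libraries and the interaction tests were fixed before the data were examined; all other tests in this part were chosen only after the result was seen. The last 5 paragraphs give differences between genotypes in an effect, each from a test of the difference itself.

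Replicate 3 lay between replicates 1 and 2 in 8 of 8 groups. Independent replicates were taken to put a given number between the other 2 in about 1 of 3 groups, a share that was assumed and not simulated. With that share the exact binomial p, allowing for any of the 3 numbers, was 0.00046. This argues against chance only if the assumed share holds and the groups vary independently. A replicate 3 made wholly of reads counted a second time would leave a residual index under 1, and the lowest was 1.21. The index does not single out replicate 3, since replicates 1 and 2 gave 1.21 to 1.71. It also cannot exclude that a part of the reads was counted again. A pool of the RNA of replicates 1 and 2, sequenced as its own library, stays open. Replicate 3 was not intermediate on every measure. Its share of reads with more than 1 alignment exceeded both others in Col-0 and bdg-8, mock and ATP, and in p2k1-3 ATP. In Col-0 ATP the shares were 4.54, 6.24 and 7.59% for replicates 1, 2 and 3. In p2k1-3 mock and in the double mutant, mock and ATP, it lay between them. A pool sequenced as its own library need not repeat these shares, so they do not decide. In 8 groups the weight of replicate 1 lay from 0.3 to 0.7. Simulated equal pools with counting noise alone gave a residual index of 0.98 to 1.04 and weights of 0.5 to 0.525. Here the index was 1.21 to 1.7 and the weight 0.375 to 0.525, so such a pool was not matched exactly. Simulated independent replicates gave an index of 3.51 to 3.75. Nothing in the labels says that replicate 3 is a pool. With simulated pools and no change, edgeR called 391 genes for ATP in p2k1-3 and 361 for the double mutant minus p2k1-3. Independent replicates gave 0 and 0. The share of genes at an unadjusted edgeR p under 0.05 was 15.8 and 15.6% with pools and 4.8 and 4.9% with independent replicates. For ATP in Col-0, simulated with some changed genes, 483 unchanged genes were called with pools and 18 with independent replicates. Far fewer genes were changed in the simulation than the 4585 called in the data, so 483 does not estimate the false calls there. A pool like the simulated one would therefore make p-values too small and add calls. Other comparisons were not examined with simulated pools.

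Of 60 genes in the stress transcription factor and pattern recognition lists, edgeR called 32 higher and 0 lower in p2k1-3 than in Col-0 without ATP, while camera called neither list with an estimated correlation (adjusted p = 0.07 and 0.053). The medians of the p2k1-3 mock libraries were 0.28, 0.57 and 0.39 against -0.04, 0.05 and 0 in Col-0 mock. The lower of p2k1-3 replicates 1 and 2 lay 0.22 above the highest Col-0 mock library, which argues against a single deviating p2k1-3 library. Leaving out p2k1-3 mock replicate 2 still lowered the genes called over all genes from 1111 to 492. The medians were 0.33, 0.26 and 0.33 in bdg-8 mock and 0.31, 0.3 and 0.41 in double mutant mock. The shift from Col-0 mock was therefore not particular to p2k1-3. With replicates 1 and 2 alone, edgeR called 8 of the 60 higher and 0 lower, and the 24 others called with all libraries kept their direction. Chance differences between the seedlings sampled stay open, since the larger camera adjusted p of the lists was 0.07 with an estimated correlation. An effect of the mutation is a biological explanation that stays open and untested, as does a difference between cultures, since the labels do not say whether replicates were grown apart.

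BDG1 rose with ATP where bdg-8 was present, with an interaction of 2.88 ± 0.10. The larger interaction of the 2 genes next to it in the order of identifiers was 0.19 ± 0.19, which argues against transcription from these neighbours. The cutin and wax list had a median interaction of 0.05, with 32 genes from -0.97 to 0.8, which argues against a general rise of these genes. Resampling the genes gave a 95% interval of -0.11 to 0.12 for this median. That interval treats the genes as independent and holds no spread between samples. A response that belongs to the bdg-8 allele may explain the rise and was not tested, because the structure of the allele is not given in the sources used here.

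Other ways of splitting the compared libraries were counted. For comparisons of 2 groups, 10 splits are too few for a share under 0.05. The real split and the highest other gave 3892 and 0 genes for ATP in Col-0, 4483 and 0 in p2k1-3, 6660 and 0 in bdg-8, and 6576 and 0 in the double mutant, each the 1 split with as many. Without ATP they gave 7000 and 0 for bdg-8 against Col-0, 1327 and 0 for p2k1-3 against Col-0, 6105 and 0 for the double mutant against p2k1-3, and 57 and 0 for the double mutant against bdg-8. Among 40 splits drawn for each interaction, the real split alone gave as many genes for the genotype interaction (291, highest other 197), the ATP response of p2k1-3 minus Col-0 (815, highest other 112) and the double mutant minus bdg-8 (146, highest other 135). For bdg-8 minus Col-0, 2 of 40 splits gave as many (1449 real, 5487 highest other), and for the double mutant minus p2k1-3, 3 of 40 did (3716 real, 7203 highest other). These splits exchanged genotypes within each treatment, or within each background for the genotype interaction. Of the other splits, 167 mixed the genotypes in both parts and 0 of these called a gene, while 28 left the genotypes of 1 part whole, so that a real difference between them entered, and 26 of these called genes. The split with 5487 genes, several times the real count, points to this structure, since it left the genotypes of the ATP libraries whole. The outcome therefore followed from which libraries were moved, and these counts neither exclude chance nor speak for it.

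The genotype interaction without ATP called 416 genes. Values above the sum of the single effects were 4.49 for AT2G01422, which stood at 0.0739 CPM in p2k1-3 mock, 1.43 for AT1G55990 and 1.31 for MBP2, with 0.97 for AT4G33610 and 0.93 for the myrosinase gene TGG2. Values below it were -3.33 for TAT3, -2.73 for AT1G05675, -2.69 for PP2-B14, -2.65 for AT1G26420 and -2.55 for AT5G52760. Among list members, WRKY30 was at -3.60, MYB51 at -1.26, CYP81F2 at -1.52, SOBIR1 at -0.94, SARD1 at -1.81 and CBP60g at -1.73.

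The ATP response of p2k1-3 differed from that of Col-0 in 940 genes. It was higher by 1.25 for GSTU24, 1.1 for ChlAKR, 1.02 for CYP81D11, 0.99 for NPC4 and 0.95 for AT3G06390. It was lower for TAT3 (-5.27), AT3G44870 (-4.25), ERF13 (-3.54), AT1G56060 (-3.43) and CYP706A2 (-3.41). In the jasmonate and calcium lists, JAZ10 and ACA13 were both at -1.72, AOC3 at -1.13 and CPK28 at -0.80. In the lists of defence, WRKY30 was at -4.49, PROPEP3, a danger peptide precursor gene, at -3.52, SARD1 at -1.96, CYP81F2 at -1.58, MYB51 at -1.51 and PAD4 at -0.90.

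The ATP response of bdg-8 differed from that of Col-0 in 1660 genes. After BDG1, higher responses were 2.61 for JAZ7, 2.05 for SWEET10, 1.88 for AT4G27657 and 1.85 for FRK1. Lower responses were -3.30 for TAT3, -3.18 for AT2G14247, -2.90 for FAMT, -2.51 for AT5G24200 and -2.25 for PKS4. Among list members, LOX3 was higher by 1.43, JAZ2 by 0.64, CPK28 by 0.92 and CPK32 by 0.85. MYB44 was higher by 0.53, WRKY11 by 0.50, MPK3 by 0.87 and MKK4 by 0.65.

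The ATP response of the double mutant differed from that of bdg-8 in 134 genes. Higher responses were 3.42 for NATA1, 2.83 for AIG1, 2.38 for both PBS3 and AT5G24200, and 1.45 for the storage protein gene VSP2. Lower responses were -3.50 for CML39, -1.51 for both AT5G19110 and ERF13, -1.47 for AT5G35940 and -1.36 for AT2G34350.

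The ATP response of the double mutant differed from that of p2k1-3 in 3406 genes. Higher responses were 3.89 for FRK1, 3.76 for AT2G17740, 3.73 for AT1G05675, 3.63 for AT5G36925 and 3.55 for AT5G36907. Lower responses were -4.03 for PR1, whose p2k1-3 replicates with ATP disagreed widely, -3.90 for AT2G14247, -3.26 for AT2G04050, -2.38 for PDF1.2 and -1.69 for PKS4. Among jasmonate and calcium genes, LOX3 was higher by 2.08, JAZ1 by 1.64, CPK28 by 1.46 and CPK32 by 1.14. Among genes of defence, WRKY30 was higher by 4.02, CYP71A12 by 2.96, SARD1 by 2.67, CBP60g by 2.38, SOBIR1 by 1.98, WRKY48 by 1.83, GSTF6 by 1.72 and MPK3 by 1.37.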

How the results depend on the processing

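Fits on pairs of replicates were chosen only after the data had been seen, and the other alternatives before the data were examined. With DESeq2, the double mutant against bdg-8 without ATP had 216 called genes (140 with edgeR), and the ATP response of the double mutant minus bdg-8 had 223 (134). With the replicate number as a block, the double mutant against bdg-8 had 273, and with only the groups compared in the fit it had 57. Other totals, from these fits, DESeq2 size factors and no filter on low counts, stayed within 1.5 times the reported value, but counts in 1 direction moved more. With the block, p2k1-3 against Col-0 without ATP had 646 lower genes (396 reported), the genotype interaction 186 higher (120), the ATP response of p2k1-3 minus Col-0 280 higher (143) and that of the double mutant minus bdg-8 158 lower (102). With only the groups compared, these had 599 lower, 78 higher, 143 higher and 75 lower, with 71 higher (32) for the double mutant minus bdg-8 and 14 higher and 43 lower (80 and 60) for the double mutant against bdg-8. The numbers were not taken to pair the samples in the main fit. In 0 of 28 pairs of groups did every same-number correlation exceed 0.1 (range -0.14 to 0.25, median 0.03). That rule cannot decide against pairing. Replicate 3 lay between the others, near its group mean, and was at -0.01 to 0.09, so it failed the rule in every pair. Replicates 1 and 2 reached 0.25 and 0.19 between Col-0 ATP and bdg-8 mock. Over all pairs of groups, a library correlated best with its own number in 100 of 168 comparisons. The same 24 libraries recur in these comparisons, and deviations from a group mean are linked within a group. The share that unrelated numbers would give is therefore not known, and the count does not decide. A partial sharing by number is not excluded.

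With replicates 1 and 2 alone, ATP called 2494 genes in Col-0, 1883 in p2k1-3, 4852 in bdg-8 and 4269 in the double mutant. Without ATP, 3170 were called for bdg-8 against Col-0, 85 for p2k1-3 against Col-0, 2161 for the double mutant against p2k1-3 and 6 for the double mutant against bdg-8. The genotype interaction had 2, and the ATP responses differed in 149 genes for p2k1-3 minus Col-0, 458 for bdg-8 minus Col-0, 2 for the double mutant minus bdg-8 and 1267 for the double mutant minus p2k1-3. The bdg-8 effects shared 1354 genes in place of 4523. The genes that fell with ATP in Col-0 had a median bdg-8 effect of -0.015, which fry no longer called.

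Replicates 1 and 3 alone gave 583 genes for p2k1-3 against Col-0 without ATP and 302 for the double mutant against bdg-8. Replicates 2 and 3 alone gave 2135 and 212, and 413 for the ATP response of the double mutant minus bdg-8. There, the genes that rose with ATP in Col-0 had a median bdg-8 effect of -0.039, now called, and those that fell 0.025, the reverse of the reported -0.022.

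Leaving out 1 library at a time moved some counts by more than 1.5 times. For p2k1-3 against Col-0 without ATP the range was 492 to 1275 genes, with 660 without Col-0 mock replicate 2, 596 without Col-0 mock replicate 3, 492 without p2k1-3 mock replicate 2 and 605 without p2k1-3 mock replicate 3. The genotype interaction ranged from 250 to 585, with 275 without Col-0 mock replicate 3, 250 without bdg-8 mock replicate 1 or p2k1-3 mock replicate 2, 271 without p2k1-3 mock replicate 3 and 268 without double mutant mock replicate 3. The double mutant against bdg-8 ranged from 40 to 215, with 66 and 57 without bdg-8 mock replicates 2 and 3, and 40, 215 and 63 without double mutant mock replicates 1, 2 and 3. The ATP response of the double mutant minus bdg-8 ranged from 67 to 150, with 86 and 80 without bdg-8 replicate 3 of mock and ATP, and 67 and 80 without double mutant replicate 3 of mock and ATP. Counts of genes changed at least 2 fold moved as well. For the double mutant against bdg-8 the 25 became 15 without bdg-8 mock replicate 2 and 12 without double mutant mock replicate 1. Without p2k1-3 mock replicate 2, the 215 of p2k1-3 against Col-0 became 143 and the 158 of the genotype interaction 99. Without double mutant mock replicate 3, the 30 of the double mutant minus bdg-8 became 19.

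The median bdg-8 effect on genes that fell with ATP in Col-0 ranged from -0.057 without Col-0 ATP replicate 2 to 0.019 without Col-0 ATP replicate 1. Its call was lost at -0.023 without Col-0 mock replicate 2, and at -0.018 and -0.023 without double mutant mock replicates 1 and 2. For genes that rose it ranged from -0.026 without p2k1-3 mock replicate 1, where it was called, to 0.009 without p2k1-3 mock replicate 2.

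Of 234 list tests, camera called 103 with the preset correlation and 20 with the estimated correlation. It called 95 with replicates 1 and 2 alone and 106 without the filter, of which 95 and 100 were among the 103 in the same direction. With the replicate block, 2 of the 103 calls were lost and none was gained, those of calcium genes in the double mutant against p2k1-3 without ATP (camera adjusted p = 0.061) and root hair markers in the ATP response of the double mutant minus bdg-8 (camera adjusted p = 0.057). No called value of a named gene changed direction in any alternative. Replicates 1 and 2 alone ended 275 calls of named genes. Another 844 values kept their side of the threshold, but these include genes called in neither fit, so the numbers give no share of calls lost. For ATP in bdg-8, 65 of 72 calls of named genes were kept. For the ATP response of the double mutant minus bdg-8, 0 of 18 were.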

Other observations

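The anthocyanin list and its tests were chosen only after anthocyanin genes had been seen among the largest rises of the double mutant against p2k1-3 without ATP; what bdg-8 against Col-0 would show was written down before that comparison was tested. Anthocyanins are red and purple flavonoid pigments whose synthesis genes are switched on together by a complex with the MYB factors PAP1 and PAP2 and the bHLH factor TT8. Of 14 genes listed, 13 were tested. In bdg-8 against Col-0 without ATP 12 rose and 1 was not called, 13 rose adjusted over the list alone, and the median was 1.31 (range 0.29 to 1.67). PAP1 rose by 1.67 ± 0.24, the reductase gene DFR by 1.54 ± 0.17, the dioxygenase gene LDOX by 1.42 ± 0.16 and TT8 by 0.88 ± 0.14. The camera p was 6.9e-12, and 0.02 with an estimated correlation, which is consistent with a bdg-8 effect on these genes where P2K1 is intact. In the double mutant against p2k1-3, 12 rose with a median of 1.96, and the glutathione transferase gene GSTF12 was at 1.96 ± 0.14. The genotype interaction had a median of 0.65 (camera p = 1.5e-09, and camera p = 0.038 with an estimated correlation). In the interaction, 0 genes were called by edgeR and 10 were higher adjusted over the list alone. The interaction contains the comparison by which the list was chosen, and that choice favours a higher value. Its p-values are therefore not independent support for a difference between backgrounds.

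ATP lowered genes of this list in bdg-8. Of the 13, 11 fell, also 11 adjusted over the list alone, with a median of -0.58 (camera p = 1e-04, but p = 0.16 with an estimated correlation), PAP1 at -1.67 ± 0.24 and PAP2 at -2.23 ± 0.55. In Col-0, 1 rose with ATP, GSTF12 by 0.44 ± 0.14, and 12 were not called. The difference between these responses was called for 6 genes, all lower in bdg-8, 10 adjusted over the list alone, with a median of -0.78 (camera p = 4.9e-08, but p = 0.057 with an estimated correlation). In the double mutant 4 fell with ATP, also 4 adjusted over the list alone, with a median of -0.16 (camera p = 0.027, but p = 0.42 with an estimated correlation). Its response was above that of bdg-8 by a median of 0.42 (camera p = 1.4e-06, but p = 0.091 with an estimated correlation), with 0 genes called by edgeR and 1 higher adjusted over the list alone. In p2k1-3 against Col-0 without ATP 3 fell, 8 adjusted over the list alone, with a median of -0.45 (camera p = 2.5e-05, but p = 0.13 with an estimated correlation). This last comparison and those of the double mutant's ATP response share mock libraries with the choice of the list. That choice favours low values in p2k1-3 mock and high values in double mutant mock, so their p-values are not independent of it. Pigment was not analysed here.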
